A study of Mus musculus with 15 samples.

How the data were processed

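Poly-A RNA of 15 mouse hearts, 3 in each of 5 groups, was sequenced as paired reads of 150 bases on an Illumina NovaSeq, per the labels. The labels call the 3 libraries of a group independent biological replicates. Intervals and tests therefore cover the spread between animals together with that of library preparation and sequencing. CASAVA, a tool for base calling, was listed, reads were mapped to GRCm38/mm10 with HISAT2 2.0.5 and counted over genes with featureCounts 1.5.0-p3, per the labels. The labels also list DESeq2 1.20.0 without stating what it was used for. The values deposited by the authors were FPKM, beside a column of gene lengths per the file headers, and the labels do not state how the FPKM were computed. The table held 54532 genes.

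FPKM multiplied by gene length gave whole reads in 100% of values above 0, within 0.05 reads, once the size of each library was solved for. This recovered between 13218352 and 15912700 reads in genes per library. The library sizes that the authors divided by differed from these sums by factors of 0.908 to 1.13, so the deposited FPKM carried a scaling between libraries whose origin the labels do not state. The median was 243.2 reads per tested gene and library, and the tenth percentile 9.4. Mitochondrially encoded genes held between 12.2% and 19.2% of the reads. No column of the table was left unused. Genes that share a symbol with another gene (203) were tested under their own identifiers. Mouse gene positions are those of GRCm38.

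Tests were made in R 4.3.3 with limma 3.58.1 on log2(FPKM + 0.5), for genes with at least 0.5 FPKM in at least 3 of the 15 libraries, which left 15321 genes. The 5 groups entered 1 linear model with 10 residual degrees of freedom, followed by empirical Bayes moderation with a trend of variance on mean level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each of 10 comparisons, of which 6 were the main ones. The pseudocount pulls folds of low genes towards 0. The median standard error of a log2 fold change in the main comparisons was 0.148. Fold changes are log2 unless stated otherwise, and adjusted p values are those of limma. The share of genes without overlap counts genes for which every library of 1 group lies above every library of the other.

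The 31 gene lists, the comparisons, the tests, the filter and the rule for named genes were written down before the data were examined. The lists were made from general knowledge of the genes. They cover fetal and stress genes, sarcomere, calcium handling, fatty acid, respiratory chain, mitochondrially encoded, tricarboxylic acid cycle, glycolysis, cell cycle, ATF4, chaperone, p53, ribosome biogenesis, ribosomal protein and matrix genes, and markers of cell types and of other tissues. They also cover cytokines, interferon-stimulated, NRF2, atrial, red blood cell, autophagy and atrophy genes. In 27 lists at least 3 members were tested. The camera test of limma asked whether a list moved relative to all other tested genes, with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. The fry test asked instead whether the members moved, on balance, in a common direction, without a comparison with other genes. Adjustment was over the lists of a comparison. Counts adjusted over the list alone apply Benjamini-Hochberg to its members only.

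Named genes followed a fixed rule. For each main comparison it took Nat10, the 8 genes that rose and the 8 that fell most, up to 4 members of each list with the smallest adjusted p, and a fixed panel of heart, stress, growth and ribosome genes. The largest changes were taken among called protein-coding genes with a mean of at least 1 FPKM in the higher group and no overlap between the groups. Names without a known function, genes of chromosome Y and Xist were left out of them. A gene named for 1 comparison may be given in another. The microRNA genes Mir320 and Gm44462 lie outside this rule and were chosen after their values were seen.

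The recovery score placed each library on the line from the CKO_GFP mean to the ff_GFP mean over the genes called between these groups. A library of either end group was left out of the line on which it was scored, but not out of the choice of genes. Scores of groups were compared with an exact permutation test, adjusted over 3 tests. Shared calls were set beside those of 20 simulations of unchanged groups, and beside the overlap of independent lists. All libraries of a simulation were drawn anew, and comparisons shared its simulated control libraries.

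The procedure was tested on simulated data with the spread and depth of these libraries, with known folds set in genes of at least 20 reads. For CKO_GFP minus ff_GFP, changes of 1.5-fold were called in 38.8% of genes, of 2-fold in 62.7% and of 4-fold in 93.9%, with 6 of 14591 unchanged genes called. For CKO_G641E minus CKO_NAT10 the shares were 28.4%, 70.1% and 93.9%, with 3 of 14514 unchanged genes called. Only 66 or 67 genes were changed at each fold. In the data 6212 genes were called for CKO_GFP minus ff_GFP, and with more changed genes the adjusted threshold is easier to pass. The simulated shares thus do not give the detection rate of that comparison. The p53 list, moved 1.5-fold down, was called (adjusted p = 2.05e-27, camera of limma) and 0 others of the 27 lists were. Genes were drawn independently here. This cannot show how often camera with the preset correlation calls unmoved lists whose genes vary together. Recovery scores simulated at 0.5 in CKO_NAT10 and CKO_G641E and at 0 in CKO_K209A were measured as 0.500, 0.506 and 0.0394.

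Alternatives tried were other pseudocounts and filters, median-ratio centring, quantile normalization, rescaling without mitochondrial and haemoglobin genes, no scaling between libraries, a replicate block, fits of the 2 groups alone, other variance models, library weights, leaving out chromosomes X and Y, Xist as a covariate, protein-coding genes only, precision weights on the recovered reads, and leaving out libraries. A count model was not run on the recovered reads.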

Results

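Poly-A RNA of 15 mouse hearts was sequenced, with 3 libraries, labelled independent biological replicates, in each of 5 groups. Pups received adeno-associated virus serotype 9 (AAV9), a vector that reaches heart muscle, under the skin on day 1 after birth, and hearts were taken 12 to 14 days later. A cardiac troponin T promoter drove the transgene. Nat10 flox/flox mice given green fluorescent protein (GFP) are called ff_GFP. Mice with a conditional knockout of Nat10 (CKO) received GFP (CKO_GFP), NAT10 (CKO_NAT10), or NAT10 carrying the substitution G641E (CKO_G641E) or K209A (CKO_K209A). NAT10 is a nucleolar enzyme that acetylates cytidine in RNA. The series title names its RNA binding and acetyltransferase activities, and the labels do not assign either substitution to either activity. Whole heart was sampled, so every value is a mean over all cell types of the tissue. In all, 15321 genes were tested with limma. The first principal component, which held 51.0% of the variance, set the libraries of CKO_GFP and CKO_K209A apart from those of the other 3 groups, and CKO_GFP replicate 1 stood apart on the second, which held 9.95%. CKO_NAT10 replicate 2 and CKO_G641E replicate 2 also lay on its side of the second component, at -23.0 and -27.4, away from the other libraries of their groups at -7.03 or above. Xist, read from the inactive X chromosome of females, was high in ff_GFP replicate 1, CKO_GFP replicates 1 and 2 and CKO_NAT10 replicate 2.

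Nat10 itself (ENSMUSG00000027185, chromosome 2, 103721256 to 103761270 on GRCm38) was read in every group, at low levels. It measured 4.09 ± 0.207 FPKM in ff_GFP, 3.48 ± 0.0498 in CKO_GFP, 2.62 ± 0.497 in CKO_NAT10, 2.36 ± 0.199 in CKO_G641E and 3.54 ± 0.291 in CKO_K209A (SD, n = 3). FPKM counts fragments per unit length of gene and per unit of library depth. The log2 change in CKO_GFP against ff_GFP was -0.21 (SE 0.11, adjusted p = 0.165), so loss of the transcript was not detectable in whole heart. None of the groups given NAT10 was called higher in Nat10 reads than CKO_GFP. CKO_NAT10 had fewer (log2 -0.36, adjusted p = 0.0262), as had CKO_G641E (-0.48, adjusted p = 0.00599). CKO_K209A differed by 0.02 (adjusted p = 0.935). The call in CKO_NAT10 ended without CKO_NAT10 replicate 2 (-0.22), and also without CKO_GFP replicate 2 or 3. The table holds no separate entry for the transgenes, so their levels in the 3 groups are unknown.

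**Figure D1:**
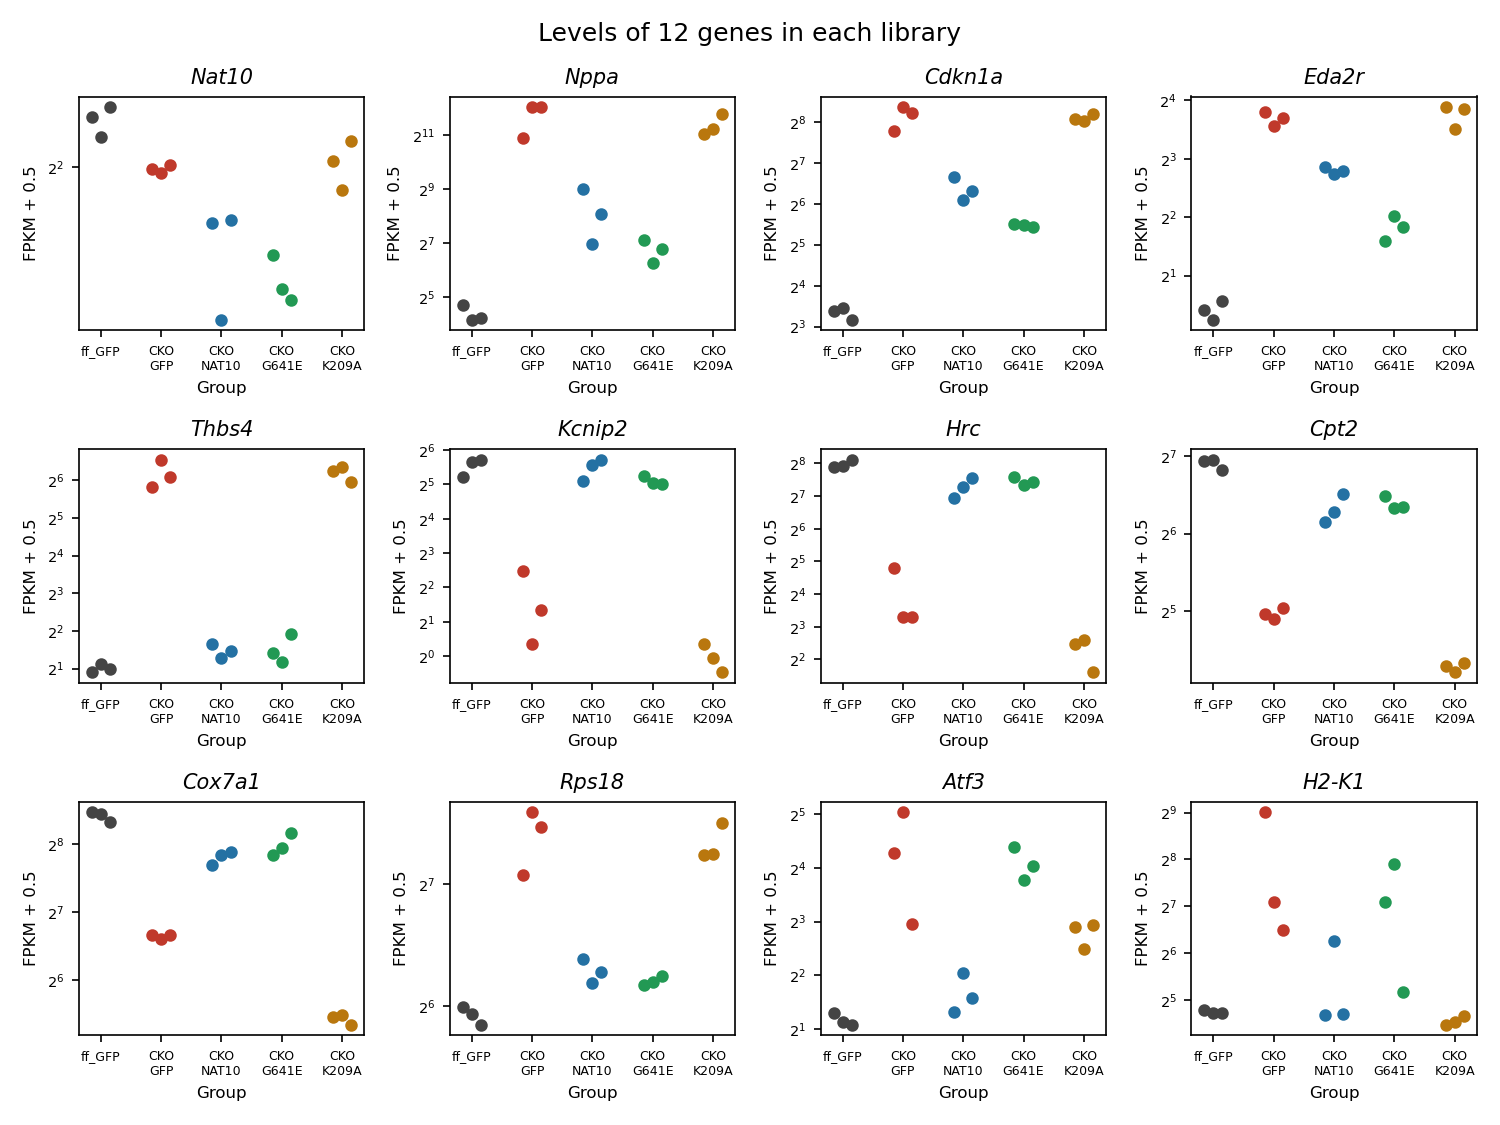
FPKM plus 0.5 on a log2 axis for 12 genes, with 1 point per library and 3 libraries per group. Nppa and Thbs4 are high, and Kcnip2 and Hrc low, in CKO_GFP and CKO_K209A against the other 3 groups.

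The comparison of CKO_GFP with ff_GFP asked what the Nat10 knockout does to the heart of pups. The knockout hearts had high levels of stress genes, of p53 target genes and of matrix genes. Levels were low for genes of fatty acid oxidation and calcium handling and for nuclear genes of the respiratory chain. Nppa, which encodes the atrial natriuretic peptide, measured 3399 ± 1301 FPKM against 20.7 ± 4.62 (SD, n = 3; log2 7.26, SE 0.44, adjusted p = 1.07e-07). Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, measured 283 ± 56.5 against 9.64 ± 1.05 FPKM (log2 4.79, SE 0.15, adjusted p = 1.59e-09). Kcnip2, which encodes a subunit of the transient outward potassium channel, measured 2.62 ± 2.20 against 46.3 ± 8.35 FPKM (log2 -4.15, SE 0.39, adjusted p = 3.53e-06). In all, 6212 genes changed, 40.5% of those tested, with 3032 higher and 3180 lower. Of these, 1651 changed at least 2-fold, 783 up and 868 down. Without scaling between libraries, which moved the median of all genes by 0.12, 4192 were higher and 2259 lower. The libraries of the 2 groups did not overlap for 46.5% of genes, where chance gives 10%.

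Among fetal and stress genes of heart muscle, 14 of 18 tested rose, 1 fell and 3 were not called, and the counts adjusted over the list alone were 14 and 1 (camera adjusted p = 2.73e-07). With an estimated correlation the list had adjusted p = 0.061. Nppb rose by log2 3.12, Ankrd1 by 3.07, Acta1 by 2.02 and Myh7 by 1.56. The largest rises among genes picked by size included Gdf15 (5.59), whose CKO_GFP level varied widely (59.1 ± 59.0 FPKM against 0.366 ± 0.0377), Ctgf (5.17), Thbs4 (5.15), Sprr1a (5.02) and Tent5b (4.45). The p53 targets rose in 20 of 23, with 3 not called and the same 20 adjusted over the list alone (camera adjusted p = 8.16e-14, and adjusted p = 0.00303 with an estimated correlation). Beside Cdkn1a these included Eda2r (log2 3.28), Phlda3 (2.90) and Mdm2 (1.42). Of 28 genes of the amino acid response and the transcription factor ATF4, 18 rose, 1 fell and 9 were not called, with 18 and 1 adjusted over the list alone (camera adjusted p = 1.71e-05, and adjusted p = 0.0475 with an estimated correlation). Atf3 rose by 2.92, Ppp1r15a by 2.63 and Slc7a5 by 2.20.

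Genes of the ribosome moved up together in CKO_GFP. Of 79 cytosolic ribosomal protein genes, 74 rose and 5 were not called, and 75 rose adjusted over the list alone (median log2 0.85, camera adjusted p = 1.18e-26). With an estimated correlation this list had adjusted p = 0.111. Rps18 rose by 1.46 and Rpsa by 1.26. Rpl3l, a muscle-specific paralogue of Rpl3, fell by 4.22. Of 58 ribosome biogenesis genes, 47 rose, 1 fell and 10 were not called, with 47 and 1 adjusted over the list alone (median 0.52, camera adjusted p = 1.17e-12, and adjusted p = 0.0475 with an estimated correlation). Rrp12 rose by 1.81 and Fbl, the methyltransferase fibrillarin, by 0.74. Thumpd1, whose product partners NAT10 in tRNA acetylation, rose by 0.51.

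Most genes of the tricarboxylic acid cycle, fatty acid and nuclear respiratory chain lists fell. All 20 genes of the tricarboxylic acid cycle fell, with the same 20 adjusted over the list alone (median log2 -1.06, camera adjusted p = 1.52e-16). This list had adjusted p = 0.0502 with an estimated correlation. For fatty acid uptake and oxidation, 26 of 32 fell and 6 were not called, and 28 fell adjusted over the list alone (median -1.21, camera adjusted p = 1.02e-16, and adjusted p = 0.0475 with an estimated correlation). Cpt2 fell by 1.94, Hadh by 1.81, Acsl1 by 1.51 and Cpt1b by 1.07, whereas the fatty acid transporter Cd36 was not called (-0.36, adjusted p = 0.0825). Of 73 nuclear genes of the respiratory chain, 65 fell and 8 were not called, and 70 fell adjusted over the list alone (median -0.65, camera adjusted p = 7.49e-24). The value was adjusted p = 0.061 with an estimated correlation. Cox7a1 fell by 1.77, Ndufs1 by 1.21 and Atp5a1 by 1.14. None of 13 mitochondrially encoded mRNAs was called (median -0.43, camera adjusted p = 0.114, but adjusted p = 0.00543 for the list without CKO_GFP replicate 2), and neither was the regulator Ppargc1a (-0.43, adjusted p = 0.148). The insulin-responsive glucose transporter gene Slc2a4 fell by 1.84, and Slc2a1, the transporter gene common in fetal heart, rose by 2.68.

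In the contractile and electrical lists, 21 of 27 calcium handling and channel genes fell and 6 were not called, with 22 down adjusted over the list alone (camera adjusted p = 2.19e-09, and adjusted p = 0.0475 with an estimated correlation). Hrc, a calcium-binding protein gene of the sarcoplasmic reticulum, fell by 4.19, Kcnh2 by 2.32 and the calcium pump gene Atp2a2 by 1.56. Ryr2 was not called (-0.18, adjusted p = 0.45). Of 23 sarcomere genes of the mature ventricle, 17 fell, 2 rose and 4 were not called, with 17 and 2 adjusted over the list alone (camera adjusted p = 1.71e-05). This list had adjusted p = 0.105 with an estimated correlation. Myh6, which encodes the adult myosin heavy chain, fell from 6105 ± 777 to 2655 ± 433 FPKM, Myl2 fell by 1.03 and Tnni3 by 0.95.

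Matrix genes rose in 31 of 34, with 3 not called and 33 up adjusted over the list alone (camera adjusted p = 1.19e-17, and adjusted p = 0.0475 with an estimated correlation). In log2 units Col8a1 rose by 3.41, Col12a1 by 3.09, Postn by 2.61, Timp1 by 1.91 and Col1a1 by 1.24. Of 13 fibroblast identity markers, 7 rose and 1 fell (camera adjusted p = 0.0654, but 0.0142 without CKO_GFP replicate 3, and fry adjusted p = 0.000856). For 18 macrophage markers, 9 rose and 9 were not called, with 9 up adjusted over the list alone (camera adjusted p = 0.00473). This had adjusted p = 0.435 with an estimated correlation. Lgals3 rose by 3.19. Among 16 cytokines and chemokines 4 rose (camera adjusted p = 0.16). Of 15 endothelial markers, 3 rose and 5 fell (camera adjusted p = 0.848). Among 38 cell cycle genes 1 rose and 1 fell (camera adjusted p = 0.345). This list was at 0.26 above the mean of all libraries in CKO_GFP replicate 1, and at -0.80 and -1.19 in replicates 2 and 3. It was called lower without CKO_GFP replicate 1 (median -0.78, adjusted p = 0.00116) and without ff_GFP replicate 1 (-0.69, adjusted p = 0.00877). Among 27 interferon-stimulated genes none was called. That last list had a median of 1.87 above the mean of all libraries in CKO_GFP replicate 1, and of -0.61 and -0.79 in replicates 2 and 3.

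The camera test called none of the other lists prepared in advance in CKO_GFP. Glycolysis genes rose in 6 of 21 and fell in 5 (camera adjusted p = 0.766), and NRF2 target genes rose in 7 of 17 and fell in 4 (camera adjusted p = 0.532). Chaperones of the endoplasmic reticulum fell in 7 of 19 and rose in 1 (camera adjusted p = 0.143). Autophagy and lysosome genes rose in 8 of 20 and fell in 5 (camera adjusted p = 0.16), and ubiquitin ligase and atrophy genes rose in 3 of 11 and fell in 2 (camera adjusted p = 0.639). Atrial genes rose in 2 of 7 and fell in 4 (camera adjusted p = 0.345). The fry test, which does not compare a list with other genes, called these chaperone, autophagy and atrial lists (adjusted p = 0.044, 0.0084 and 0.00638). Without CKO_GFP replicate 1 camera called the chaperones, with a median of -0.46, and the autophagy genes, with 0.19 (adjusted p = 0.0193 and 0.0346). Smooth muscle and pericyte markers rose in 3 of 12 and fell in 4 (camera adjusted p = 0.766). None of 6 lymphocyte and neutrophil markers was called (camera adjusted p = 0.532), nor any of 8 red blood cell genes (camera adjusted p = 0.936). Of the markers of other tissues, no lung gene, 1 adipose gene, 2 thymus genes and 1 liver gene passed the filter, too few for a list test.

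**Figure D2:**
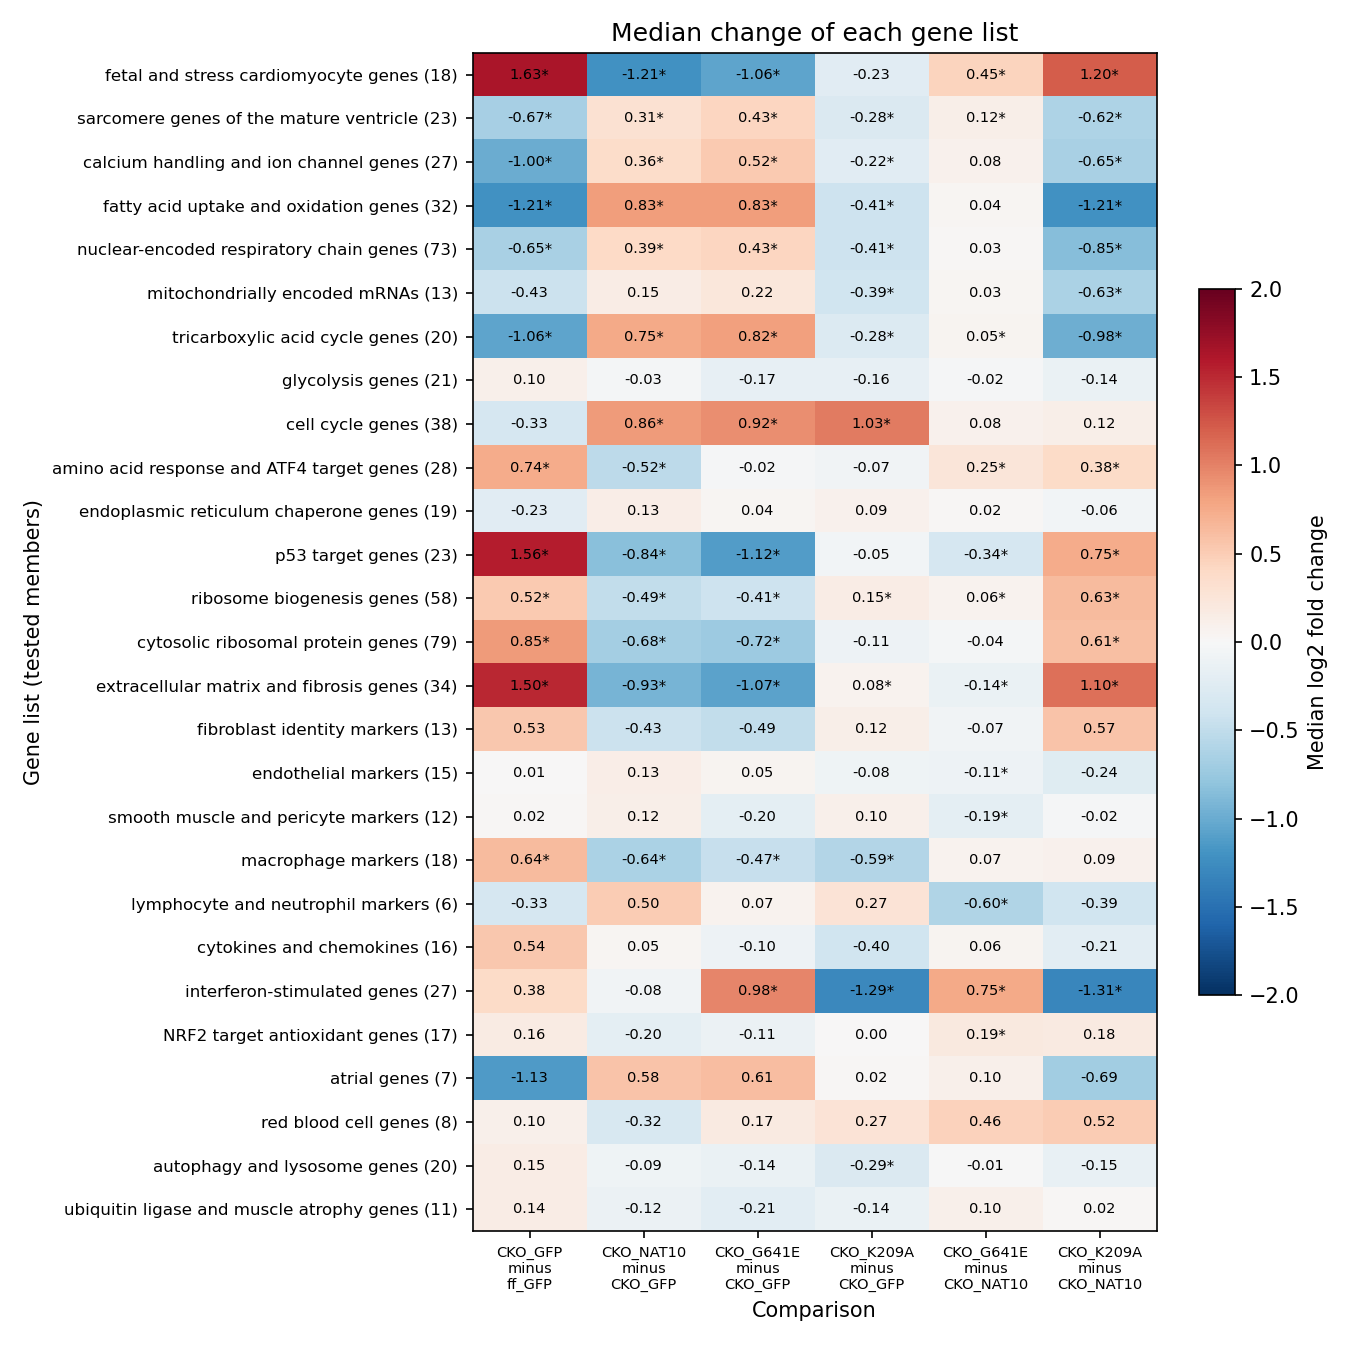
Median log2 fold change of each gene list in the 6 main comparisons, with the number of tested members in parentheses. A star marks a camera adjusted p under 0.05 with the preset correlation; the medians of p53 target genes run from 1.56 in CKO_GFP minus ff_GFP to -1.12 in CKO_G641E minus CKO_GFP.

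The comparison of CKO_NAT10 with CKO_GFP asked how far NAT10 delivered to the heart reversed these changes. Stress, p53, ribosome and matrix genes were lower than in CKO_GFP. Genes of fatty acid oxidation, the tricarboxylic acid cycle, the respiratory chain and calcium handling were higher. Camera called 13 of 27 lists with the preset correlation and 1, the p53 targets, with an estimated correlation. Nppa fell from 3399 ± 1301 to 302.9 ± 197 FPKM (SD, n = 3; log2 -3.62, SE 0.44, adjusted p = 6.55e-05), still above the 20.7 FPKM of ff_GFP. Kcnip2 rose from 2.62 ± 2.20 to 44.3 ± 9.56 FPKM (log2 4.08, SE 0.39, adjusted p = 1.31e-05), near the 46.3 ± 8.35 of ff_GFP. Thbs4 fell from 72.1 ± 18.9 to 2.30 ± 0.364 FPKM (log2 -4.68, SE 0.20, adjusted p = 9.39e-08). In total 4776 genes changed, 2316 up and 2460 down, and 946 of them at least 2-fold. The 2 groups fitted alone gave 2355 genes. Libraries did not overlap for 38.9% of genes, where chance gives 10%.

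Sprr1a fell by 4.93, Serpinb1c by 4.14, Tent5b by 4.03, Ankrd2 by 3.88 and Ctgf by 3.73, and Hrc rose by 3.48, Rtn4r by 3.32, Asb15 by 3.04 and Art1 by 2.98. The fetal and stress list had 14 genes down, 2 up and 2 not called, with 14 and 2 adjusted over the list alone (camera adjusted p = 1.05e-06). With an estimated correlation it had adjusted p = 0.09. Ankrd1 fell by 1.42 and Nppb by 1.88, whereas Acta1 differed by -0.26 (adjusted p = 0.677). Of 23 p53 targets 16 fell and 7 were not called, and 17 fell adjusted over the list alone (camera adjusted p = 1.5e-09, and adjusted p = 0.0145 with an estimated correlation). Cdkn1a fell by 1.76, to 83.0 ± 16.3 FPKM, and Mdm2 by 0.84. Of the ATF4 list 14 fell, 1 rose and 13 were not called, with 15 down and 2 up adjusted over the list alone (camera adjusted p = 0.000251). Its value was adjusted p = 0.09 with an estimated correlation. Atf3 fell by 2.44 and Ppp1r15a by 2.27.

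Ribosomal protein genes fell in 75 of 79, with 4 not called and 76 down adjusted over the list alone (median log2 -0.68, camera adjusted p = 3.88e-27). With an estimated correlation they had adjusted p = 0.118. Ribosome biogenesis genes fell in 44 of 58 and rose in 1, with 13 not called, and with 49 down and 1 up adjusted over the list alone (camera adjusted p = 5.59e-16). The value was adjusted p = 0.0612 with an estimated correlation. Rps18 fell from 168 ± 30.0 to 77.5 ± 5.36 FPKM, and Thumpd1 fell by 0.47. All 20 genes of the tricarboxylic acid cycle rose, also adjusted over the list alone (median 0.75, camera adjusted p = 4.37e-16, but adjusted p = 0.0746 with an estimated correlation). Fatty acid genes rose in 25 of 32, with 7 not called and 26 up adjusted over the list alone (camera adjusted p = 3.53e-15, but adjusted p = 0.0612 with an estimated correlation). Respiratory chain genes rose in 54 of 73, with 19 not called and 56 up adjusted over the list alone (camera adjusted p = 7.35e-18, but adjusted p = 0.116 with an estimated correlation). Cpt2 rose by 1.35, Cox7a1 by 1.16 and Slc2a4 by 1.40, and Slc2a1 fell by 1.94.

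Calcium handling and channel genes rose in 14 of 27, fell in 1 and were not called in 12, with 15 up and 1 down adjusted over the list alone (camera adjusted p = 1.06e-05, but adjusted p = 0.09 with an estimated correlation). Sarcomere genes rose in 11 of 23, fell in 2 and were not called in 10, with 13 up and 3 down adjusted over the list alone (camera adjusted p = 0.00251, but adjusted p = 0.29 with an estimated correlation). Atp2a2 rose by 0.95. Myh6 rose by 0.76, a call that ended with quantile normalization (adjusted p = 0.168). Matrix genes fell in 30 of 34, with 4 not called and 31 down adjusted over the list alone (median log2 -0.93, camera adjusted p = 1.71e-16, but adjusted p = 0.0746 with an estimated correlation). Postn fell by 1.59 and Col1a1 by 0.79. Of the 13 fibroblast identity markers 7 fell and 2 rose, with the same counts adjusted over the list alone (median -0.43, camera adjusted p = 0.294, fry adjusted p = 0.027). Cell cycle genes rose in 4 of 38, with 1 up adjusted over the list alone (median 0.86, camera adjusted p = 1.2e-05, but adjusted p = 0.558 with an estimated correlation). CKO_GFP replicate 1 stood apart in this list, and the median was 1.31 without it and 0.52 without CKO_GFP replicate 3 (adjusted p = 9.25e-11 and 0.00406). Macrophage markers fell in 7 of 18 (camera adjusted p = 0.00227, but adjusted p = 0.378 with an estimated correlation).

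The comparison of CKO_G641E with CKO_GFP asked whether NAT10 with the G641E substitution could act in the same way. Stress, p53, ribosome and matrix genes were again lower. Genes of fatty acid oxidation, the tricarboxylic acid cycle, the respiratory chain and calcium handling were again higher. Camera called 13 of 27 lists with the preset correlation and 1, the p53 targets, with an estimated correlation. The ATF4 list was not called by camera here. In CKO_NAT10 it was called lower with the preset correlation alone (adjusted p = 0.09 with an estimated correlation). Nppa fell to 109.0 ± 30.5 FPKM from 3399 ± 1301 (SD, n = 3; log2 -4.91, SE 0.44, adjusted p = 6.79e-06). Cdkn1a fell to 44.1 ± 1.05 FPKM from 283 ± 56.5 (log2 -2.65, SE 0.15, adjusted p = 4.92e-07). Hrc rose to 175 ± 16.8 FPKM from 15.2 ± 10.4 (log2 3.66, SE 0.35, adjusted p = 1.09e-05). The total was 4793 genes, 2352 up and 2441 down, with 1010 changed at least 2-fold. The 2 groups fitted alone gave 2703 genes. Libraries did not overlap for 39.9% of genes, where chance gives 10%.

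Thbs4 fell by 4.64, Tent5b by 4.43, Sprr1a by 4.33, Ass1 by 3.75 and Fmod by 3.69, and Kcnip2 rose by 3.71, Rtn4r by 3.28, Art1 by 3.23 and Rpl3l by 3.11. Of 23 p53 targets 19 fell and 4 were not called, with 20 down adjusted over the list alone (median log2 -1.12, camera adjusted p = 5.32e-14, and adjusted p = 0.00286 with an estimated correlation). The fetal and stress list had 12 down, 2 up and 4 not called, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.000478, but adjusted p = 0.226 with an estimated correlation). Ankrd1 fell by 1.26, Nppb fell to 588 ± 172 FPKM from 1351 ± 385, and Acta1 differed by -0.09 (adjusted p = 0.889). In the ATF4 list 10 fell, 3 rose and 15 were not called, with the same counts adjusted over the list alone (median -0.02, camera adjusted p = 0.269, but fry adjusted p = 0.0272). Atf3 stayed near the CKO_GFP level (-0.02, adjusted p = 0.975) and Asns rose by 1.05 (adjusted p = 0.0389), a call that ended without any 1 of the 3 CKO_G641E libraries and without CKO_GFP replicate 2 or 3.

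Ribosomal protein genes fell in 72 of 79, with 7 not called and 75 down adjusted over the list alone (camera adjusted p = 1.32e-27, but adjusted p = 0.131 with an estimated correlation). Ribosome biogenesis genes fell in 40 of 58, rose in 1 and were not called in 17, with 42 and 1 adjusted over the list alone (camera adjusted p = 7.96e-13, but adjusted p = 0.0623 with an estimated correlation). The tricarboxylic acid cycle genes rose in 20 of 20, also adjusted over the list alone (median log2 0.82, camera adjusted p = 7.45e-17, but adjusted p = 0.0658 with an estimated correlation). Fatty acid genes rose in 25 of 32, with 26 up adjusted over the list alone (camera adjusted p = 3.01e-16, but adjusted p = 0.0623 with an estimated correlation). Respiratory chain genes rose in 56 of 73, with the same 56 up adjusted over the list alone (camera adjusted p = 2.62e-19, but adjusted p = 0.127 with an estimated correlation). Cpt2 rose by 1.42 and Cox7a1 by 1.34. Calcium handling and channel genes rose in 16 of 27 and sarcomere genes in 13 of 23, with 17 up in each list adjusted over the list alone. Of the sarcomere genes 1 fell, and 2 adjusted over the list alone. Their camera adjusted p values were 3.46e-06 and 3.34e-05, but 0.0944 and 0.131 with an estimated correlation. Matrix genes fell in 31 of 34, also adjusted over the list alone (median -1.07, camera adjusted p = 3.76e-19, but adjusted p = 0.0623 with an estimated correlation). Fibroblast identity markers fell in 7 of 13 and rose in 1, also adjusted over the list alone (median -0.49, camera adjusted p = 0.138, fry adjusted p = 0.0058). Macrophage markers fell in 4 of 18 (camera adjusted p = 0.0106, but adjusted p = 0.554 with an estimated correlation, 0.0608 without CKO_GFP replicate 1 and 0.0973 without CKO_G641E replicate 3). Without CKO_G641E replicate 2 their median was -0.72 (camera adjusted p = 0.000133). Cell cycle genes rose in 15 of 38, with 19 up adjusted over the list alone (median 0.92, camera adjusted p = 5.79e-06, but adjusted p = 0.586 with an estimated correlation). CKO_GFP replicate 1 was at 0.26 in this list, within the 0.22 to 0.44 of CKO_G641E, and replicates 2 and 3 at -0.80 and -1.19, and without replicate 1 the median was 1.46 (adjusted p = 7.45e-11). Interferon-stimulated genes rose in 1 of 27 (median 0.98, camera adjusted p = 0.0371, but adjusted p = 0.864 with an estimated correlation). CKO_G641E replicate 2 and CKO_GFP replicate 1 stood apart in this list, at 2.05 and 1.87 above the mean of all libraries. Without CKO_G641E replicate 2 the median was 0.39 (adjusted p = 0.449), and without CKO_GFP replicate 1, 2 or 3 it was 1.75, 0.56 or 0.48 (adjusted p = 2.35e-05, 0.26 and 0.373).

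The comparison of CKO_K209A with CKO_GFP asked the same of NAT10 with the K209A substitution. Few stress and p53 genes were called different from CKO_GFP, and several energy and calcium handling genes were lower still. Nppa measured 2659 ± 722 against 3399 ± 1301 FPKM (SD, n = 3; log2 -0.30, SE 0.44, adjusted p = 0.731). Cdkn1a measured 274 ± 17.1 against 283 ± 56.5 FPKM (log2 -0.03, SE 0.15, adjusted p = 0.936). Cox7a1 fell from 99.3 ± 2.46 to 42.7 ± 2.29 FPKM (log2 -1.21, SE 0.09, adjusted p = 1.42e-05). In all, 1215 genes changed, 333 up and 882 down, and 127 at least 2-fold. Fitted alone, these 2 groups gave 9 genes, and without CKO_K209A replicate 1 or 2 the count was 427 or 532. Xist was high in 2 of the 3 CKO_GFP libraries and in 0 of the CKO_K209A libraries, and with Xist as a covariate 511 genes were called, 75 up and 436 down. Without scaling between libraries 979 genes were higher and 479 lower, and with quantile normalization 547 and 559. The excess of falls thus varied with the scaling. Libraries did not overlap for 23.2% of genes, where chance gives 10%.

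Tnni1, a troponin I gene of slow and fetal muscle, rose by 2.37, Ap1s3 and Spp1 by 1.57 each and Gpc3 by 0.87. Dgat2 fell by 1.88, Rxrg by 1.94, Tcap by 1.62, Hrc by 1.56, Hcn2 by 1.24, Slc2a4 by 1.00 and Pln by 0.87. With the 2 groups fitted alone the call of Cox7a1 stayed (adjusted p = 0.0227), and those of the other genes named here ended. Respiratory chain genes fell in 56 of 73, with 17 not called and 67 down adjusted over the list alone (median log2 -0.41, camera adjusted p = 2.02e-35, but adjusted p = 0.186 with an estimated correlation). Their median was -0.22 with quantile normalization and -0.30 without scaling between libraries. Fatty acid genes fell in 14 of 32, with 18 down adjusted over the list alone (camera adjusted p = 4.98e-08, but adjusted p = 0.304 with an estimated correlation). Cpt2 fell by 0.69, Hadh by 0.74 and Acadm by 0.66. Tricarboxylic acid cycle genes fell in 9 of 20, with 15 down adjusted over the list alone (camera adjusted p = 5.25e-09, but adjusted p = 0.32 with an estimated correlation). Calcium handling and channel genes fell in 6 of 27, with 8 down adjusted over the list alone (camera adjusted p = 0.00469, but adjusted p = 0.436 with an estimated correlation, 0.057 without CKO_GFP replicate 3 and 0.06 without CKO_K209A replicate 3). Sarcomere genes fell in 5 of 23, with 10 down adjusted over the list alone (camera adjusted p = 0.000219, but adjusted p = 0.32 with an estimated correlation). Quantile normalization took the sarcomere list to a median of 0.00 (adjusted p = 0.738).

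Of the 13 mitochondrially encoded mRNAs, mt-Atp8 fell by 1.56, a call that ended with the 2 groups fitted alone (adjusted p = 0.0947), and 12 were not called (camera adjusted p = 0.00116, but adjusted p = 0.509 with an estimated correlation, adjusted p = 0.261 with quantile normalization, and 0.0998 without CKO_GFP replicate 2). Autophagy and lysosome genes fell in 6 of 20, with 7 down adjusted over the list alone (camera adjusted p = 6.55e-05, but adjusted p = 0.285 with an estimated correlation). Among 23 p53 targets 1 fell and 22 were not called (camera adjusted p = 0.616), and among 28 ATF4 genes 1 rose (camera adjusted p = 0.889). In the fetal and stress list 1 of 18 rose (camera adjusted p = 0.933). None of the 79 ribosomal protein genes was called (median -0.11, camera adjusted p = 0.16), and quantile normalization turned their median to 0.12 (adjusted p = 0.000536). Without CKO_GFP replicate 1 it was -0.20 and without CKO_K209A replicate 3 -0.13 (adjusted p = 1.09e-05 and 0.013). Ribosome biogenesis genes rose in 8 of 58, with 11 up adjusted over the list alone (camera adjusted p = 3.52e-05, but adjusted p = 0.345 with an estimated correlation), among them Nop58 (0.59, but adjusted p = 0.109 with the 2 groups fitted alone). Cell cycle genes rose in 4 of 38, with 18 up adjusted over the list alone (median 1.03, camera adjusted p = 2.15e-06, but adjusted p = 0.672 with an estimated correlation). CKO_GFP replicate 1 stood apart in this list, and without CKO_GFP replicate 3 the median was 0.69 (adjusted p = 0.00842). Matrix genes rose in 3 of 34, with 4 up adjusted over the list alone (median 0.08, camera adjusted p = 0.0327, but adjusted p = 0.672 with an estimated correlation, and adjusted p = 0.0528, 0.549 and 0.116 without CKO_GFP replicate 1, CKO_GFP replicate 3 or CKO_K209A replicate 2). The matrix median was 0.20, 0.13 and 0.12 without CKO_GFP replicate 2, CKO_K209A replicate 1 or CKO_K209A replicate 3 (camera adjusted p = 0.000147, 0.0248 and 0.0235). Macrophage markers fell in 4 of 18, with 8 down adjusted over the list alone (median -0.59, camera adjusted p = 0.00296, but adjusted p = 0.555 with an estimated correlation). Among genes picked by size, H2-Q6 changed by -4.69 (SE 1.05), H2-K1 by -2.97, H2-D1 by -2.55 and B2m by -2.34. They act in antigen presentation by MHC class I, for which no list was prepared or tested, and all 4 calls ended with the 2 groups fitted alone. Without CKO_GFP replicate 1 the changes were -3.66, -2.23, -1.95 and -1.71, and B2m was not called (adjusted p = 0.111). H2-K1 measured 247 ± 233 FPKM in CKO_GFP, 23.2 ± 1.65 in CKO_K209A and 26.5 ± 0.615 in ff_GFP. The 27 interferon-stimulated genes had a median change of -1.29 with none called (camera adjusted p = 0.00026, but adjusted p = 0.672 with an estimated correlation). Without CKO_GFP replicate 1, which stood apart in this list, the median was -0.31 (adjusted p = 0.333).

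The comparison of CKO_G641E with CKO_NAT10 asked what the G641E substitution changed in delivered NAT10. Few genes differed. Atf3, a stress-induced transcription factor gene, measured 16.5 ± 3.66 FPKM in CKO_G641E and 2.70 ± 0.828 in CKO_NAT10 (SD, n = 3; log2 2.42, SE 0.38, adjusted p = 0.05, just under the threshold). Eda2r, a p53 target, measured 3.04 ± 0.526 and 6.46 ± 0.287 FPKM (log2 -0.98, SE 0.13, adjusted p = 0.0192). In all 8 genes were called, 5 higher and 3 lower. At an unadjusted p under 0.05 (limma) there were 1031 of the 15321 tested, where a share of 0.05 would pass by chance alone. Cabcoco1 was higher by 1.11 (adjusted p = 0.0192), Dusp27 by 0.82 (0.037), Tlr4 by 0.79 (0.0205) and Filip1 by 0.67 (0.0194). The microRNA genes Mir320 and Gm44462 were listed at 0 in CKO_G641E. FPKM divides by gene length, so short genes can pass the filter with few reads, and a listing of 0 does not show a loss. With the 2 groups fitted alone none was called, and leaving out each of the 15 libraries in turn gave between 0 and 27 genes, with 0 without any 1 of the CKO_G641E libraries. The libraries of the 2 groups did not overlap for 15.4% of genes, where chance gives 10%.

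The intervals of this comparison were narrow for many genes. For 13451 genes, 87.8% of those tested, the 95% interval of the fold change lay within 2-fold in either direction, and the median interval reached 0.321 log2 units to each side. Of the 6212 genes changed in CKO_GFP against ff_GFP, 5876 (94.6%) had such an interval. As lists, the p53 targets were lower in CKO_G641E, with 1 of 23 called and 10 lower adjusted over the list alone (median log2 -0.34, camera adjusted p = 4.53e-14, and adjusted p = 0.00222 with an estimated correlation). Cdkn1a differed by -0.89 (adjusted p = 0.0662) and Phlda3 by -0.76 (adjusted p = 0.209). The ATF4 genes were higher, with 1 of 28 called, and with 10 higher and 1 lower adjusted over the list alone (median 0.25, camera adjusted p = 1.4e-07, and adjusted p = 0.0334 with an estimated correlation). Asns differed by 1.48 (adjusted p = 0.275) and Phgdh by 1.29 (adjusted p = 0.0808). These were the 2 of 27 lists that passed with an estimated correlation. With the preset correlation 10 more passed, among them interferon-stimulated genes (median 0.75, camera adjusted p = 8.53e-06, but adjusted p = 0.619 with an estimated correlation). The interferon median was 0.22 without CKO_G641E replicate 2 (adjusted p = 0.0926) and higher without CKO_G641E replicate 3 (adjusted p = 7.24e-11), and 0.28, 1.48 and 0.50 without CKO_NAT10 replicate 1, 2 or 3. The fetal and stress genes had a median of 0.45 (camera adjusted p = 1.97e-05, but adjusted p = 0.198 with an estimated correlation). Nppa differed by -1.29 (adjusted p = 0.543).

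The comparison of CKO_K209A with CKO_NAT10 asked what the K209A substitution changed. Many of the genes that differed were those that changed in the knockout itself. Nppa measured 2659 ± 722 against 302.9 ± 197 FPKM (SD, n = 3; log2 3.32, SE 0.44, adjusted p = 5.57e-05). Cdkn1a measured 274 ± 17.1 against 83.0 ± 16.3 FPKM (log2 1.73, SE 0.15, adjusted p = 1.77e-06). Cox7a1 measured 42.7 ± 2.29 against 223 ± 14.5 FPKM (log2 -2.37, SE 0.09, adjusted p = 2.53e-09). In total 6363 genes differed, 3111 higher and 3252 lower in CKO_K209A, and 1562 by at least 2-fold. CKO_K209A against CKO_G641E gave 6250 genes, 2998 higher and 3252 lower. Without scaling between libraries, which moved the medians by 0.11 and 0.13, the counts were 6729, with 4287 higher and 2442 lower, and 6881, with 4523 higher and 2358 lower. Libraries of CKO_K209A and CKO_NAT10 did not overlap for 54.4% of genes, where chance gives 10%. A lower level of the K209A transgene could not be told apart from an effect of the substitution, because no transgene reads were listed. Reads of the mouse gene Nat10 were higher in CKO_K209A than in CKO_NAT10 (log2 0.38, limma adjusted p = 0.0151). That call ended with the 2 groups fitted alone (adjusted p = 0.07).

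Tent5b was higher by 5.02, Ankrd2 and Thbs4 by 4.70 each, Sprr1a by 4.43, Serpina3n by 4.38 and Ap1s3 by 4.20. Kcnip2 was lower (log2 -5.52), as were Hrc (-5.04), Rtn4r (-3.93), Rxrg (-3.89) and Tcap (-3.05). Art1 was listed at 0 in all 3 CKO_K209A libraries, against 6.93 ± 3.04 FPKM in CKO_NAT10. Respiratory chain genes fell in 71 of 73, also adjusted over the list alone (median -0.85, camera adjusted p = 7.66e-31, but adjusted p = 0.0685 with an estimated correlation). All 20 tricarboxylic acid cycle genes fell, again adjusted over the list alone (camera adjusted p = 5.4e-16, but adjusted p = 0.0757 with an estimated correlation). Fatty acid genes fell in 26 of 32 and rose in 1, with the same counts adjusted over the list alone (median -1.21, camera adjusted p = 1.05e-14, but adjusted p = 0.0673 with an estimated correlation). Cpt2 fell by 2.04 and Acadm by 1.87. Calcium handling and channel genes fell in 15 of 27 and sarcomere genes in 15 of 23, with 2 up in each, and 19 and 15 fell adjusted over the list alone (camera adjusted p = 4.16e-06 and 7.88e-05). With an estimated correlation they had adjusted p = 0.0838 and 0.14. Mitochondrially encoded mRNAs fell in 7 of 13, with 8 down adjusted over the list alone (camera adjusted p = 0.00626, but adjusted p = 0.423 with an estimated correlation, and adjusted p = 0.518 with quantile normalization).

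In the opposite direction p53 targets rose in 17 of 23, also adjusted over the list alone (median log2 0.75, camera adjusted p = 2.59e-06, but adjusted p = 0.059 with an estimated correlation). Ribosome biogenesis genes rose in 49 of 58, with the same 49 adjusted over the list alone (camera adjusted p = 5.4e-16, but adjusted p = 0.059 with an estimated correlation) and ribosomal protein genes in 69 of 79, with 72 adjusted over the list alone (camera adjusted p = 3.31e-18, but adjusted p = 0.224 with an estimated correlation). Matrix genes rose in 28 of 34, with the same 28 adjusted over the list alone (camera adjusted p = 1.05e-14, but adjusted p = 0.0803 with an estimated correlation). Fibroblast identity markers rose in 7 of 13 and fell in 2, with 7 up and 3 down adjusted over the list alone (median 0.57, camera adjusted p = 0.0961, but 0.0484 without CKO_K209A replicate 3, and fry adjusted p = 0.000849). ATF4 genes rose in 14 of 28 and fell in 1, and fetal and stress genes rose in 13 of 18, with 14 up in each adjusted over the list alone (camera adjusted p = 0.00329 and 1.71e-05). With an estimated correlation both had adjusted p = 0.14. None of the 27 lists passed in this comparison with an estimated correlation. Acta1 differed by -1.02 (adjusted p = 0.0637).

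How far each heart lay between CKO_GFP and ff_GFP was measured with a recovery score over the 6212 genes, in which 0 is the CKO_GFP mean and 1 the ff_GFP mean. It was 0.722 ± 0.0562 in CKO_NAT10, 0.735 ± 0.0135 in CKO_G641E and -0.0696 ± 0.0117 in CKO_K209A (SD, n = 3). The CKO_GFP libraries, each scored against the others, gave 0.0378 ± 0.193, and ff_GFP gave 0.985 ± 0.0232. The 6212 genes were chosen with these libraries included, so the scores of these 2 groups are in part set by that choice. The scores of CKO_NAT10 and CKO_G641E differed by -0.0125 (2-sided exact permutation p = 0.9). CKO_NAT10 lay above CKO_K209A by 0.792 and CKO_G641E above CKO_K209A by 0.804, each with an exact permutation p = 0.1, the smallest that 3 against 3 libraries allow (Benjamini-Hochberg adjusted p = 0.15 over 3 tests). Without CKO_GFP replicate 1 the CKO_K209A score was 0.0258.

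**Figure D3:**
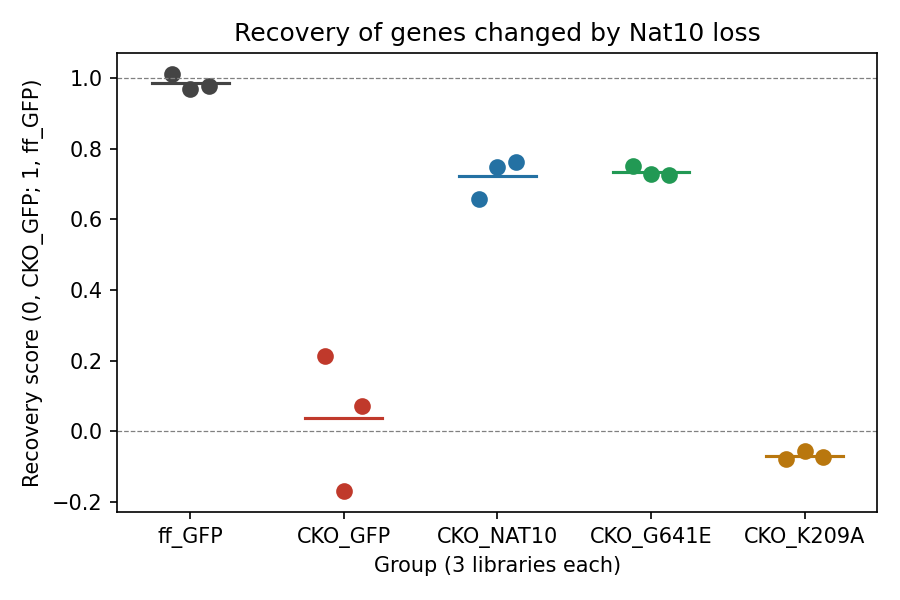
Recovery score of each library over 6212 genes, with 1 point per library, 3 libraries per group and a line at the group mean. The 6 libraries of CKO_NAT10 and CKO_G641E lie at 0.658 or above, and the CKO_GFP libraries at 0.212 or below.

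Of the 6212 genes, 4225 (68.0%) were called back towards ff_GFP in CKO_NAT10 and 4208 (67.7%) in CKO_G641E. In CKO_K209A, 152 (2.45%) were called back, and 132 rises and 509 falls went further in the same direction. These further rises and falls were 146 and 496 with median-ratio centring and 229 and 332 with quantile normalization. They were 289 and 347 when rescaled without mitochondrial and haemoglobin genes, and 468 and 262 without scaling between libraries. The size of the excess of falls thus varied with the scaling, and it turned only without scaling. Against ff_GFP, 360 of the 6212 genes (5.80%) were still called different in CKO_NAT10, 255 (4.10%) in CKO_G641E and 5212 (83.9%) in CKO_K209A. A gene not called may still differ. Adjusted over the list alone, 22 of 32 fatty acid genes and 47 of 73 respiratory chain genes were lower in CKO_NAT10 than in ff_GFP. In CKO_G641E 20 and 37 were lower, whereas 0 of 58 ribosome biogenesis genes were called in CKO_NAT10. Libraries of CKO_NAT10 and CKO_G641E did not overlap those of ff_GFP for 25.4% and 26.9% of genes, where chance gives 10%. Over all tested genes, 378 differed between CKO_NAT10 and ff_GFP and 274 between CKO_G641E and ff_GFP. Leaving out 1 library in turn moved these counts between 92 and 719 and between 70 and 579. Between CKO_K209A and ff_GFP 7307 genes differed, 3547 up and 3760 down. Without scaling between libraries, which moved this median by 0.21, there were 5639 up and 2489 down. By list, p53 targets had a score of 0.455 ± 0.0646 in CKO_NAT10 and 0.662 ± 0.00663 in CKO_G641E, and ATF4 genes had 0.776 ± 0.0354 and 0.447 ± 0.0410 (SD, n = 3; exact permutation p = 0.1 for each). Endothelial markers, at 0.836 ± 0.0464 and 0.928 ± 0.0423, also had the smallest exact p of 0.1, and over the 21 lists scored the Benjamini-Hochberg adjusted p of these 3 lists was 0.7. Matrix genes scored 0.814 ± 0.0692 and 0.848 ± 0.0513. The respiratory chain genes scored -0.558 ± 0.0409 in CKO_K209A.

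The changes in CKO_GFP minus ff_GFP and in CKO_NAT10 minus CKO_GFP shared 2164 genes that rose and then fell and 2061 that fell and then rose, where independent lists would share 487 and 481. The fold changes correlated across genes at r = -0.887, against -0.505 in 20 simulations of unchanged groups that share simulated control libraries. Their covariance was -0.355 against -0.0303. For CKO_G641E minus CKO_GFP the shared counts were 2122 and 2086, where independent lists would share 483 and 488 (r = -0.873, covariance -0.359 against -0.0302 simulated). CKO_NAT10 minus CKO_GFP and CKO_G641E minus CKO_GFP shared 1844 rises, where independent lists would share 356, and 1938 falls (r = 0.890, covariance 0.295 against 0.0301 simulated). With CKO_K209A minus CKO_GFP the changes of CKO_GFP minus ff_GFP shared 132 rises and 509 falls, a split that turned without scaling between libraries, where independent lists would share 65.9 and 183 (r = 0.0369, against -0.502 simulated, covariance 0.00991 against -0.0301). The simulations themselves shared 0 called genes. The 3 CKO_GFP libraries could not be divided into separate controls of equal size, so part of each excess may come from the shared libraries. The simulations gave a gene the same spread in all groups and drew genes independently. Pairs of CKO_GFP libraries correlated at r = 0.949 to 0.970, below the 0.977 to 0.980 of ff_GFP. The simulated covariances may thus understate what the shared libraries add. For a pair with no library in common, CKO_GFP minus ff_GFP and CKO_K209A minus CKO_NAT10, there were 2091 shared rises and 2280 shared falls, where independent lists would share 616 and 675 (r = 0.75 against 0.00242 simulated, covariance 0.365 against 0.000144). Genes are not independent replicates in these correlations.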

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

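Alternatives were listed before the data were examined, except 3 that were added after seeing the data: precision weights on the recovered reads, leaving out the 3 libraries highest in interferon-stimulated genes, and no scaling between libraries. A count model was not run. Of 330 repeats of the counts of changed genes, 292 stayed the same and 38 moved by over 1.5 times. Of the list tests 3692 stayed, 126 were weaker, 62 stronger and 2 reversed. Of named genes 4890 stayed, 161 were weaker, 26 stronger and 0 reversed, and for Nat10 311 stayed, 18 were weaker and 1 stronger. Of the overlaps 13 stayed and 5 moved, and of the recovery scores 22 stayed, 7 moved and 1 reversed. The cause was not tested for any of these.

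With the 2 groups fitted alone the count was 2355 for CKO_NAT10 minus CKO_GFP, 2703 for CKO_G641E minus CKO_GFP, 9 for CKO_K209A minus CKO_GFP, 0 for CKO_G641E minus CKO_NAT10 and 207 for CKO_NAT10 minus ff_GFP. Library weights gave 38 for CKO_G641E minus CKO_NAT10, 938 for CKO_NAT10 minus ff_GFP and 1149 for CKO_G641E minus ff_GFP. Xist as a covariate gave 511 for CKO_K209A minus CKO_GFP and 164 for CKO_G641E minus ff_GFP. CKO_G641E minus CKO_NAT10 gave 4 with a pseudocount of 0.1, 5 with a mean of at least 1 FPKM, 13 for protein-coding genes, 4 without the 3 interferon-high libraries and 4 without scaling. Leaving out 1 library at a time gave 427 to 1650 for CKO_K209A minus CKO_GFP, 0 to 27 for CKO_G641E minus CKO_NAT10, 92 to 719 for CKO_NAT10 minus ff_GFP and 70 to 579 for CKO_G641E minus ff_GFP.

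Nat10 in CKO_NAT10 minus CKO_GFP was -0.36 with the 2 groups alone, -0.34 with library weights and -0.22 without the interferon-high libraries (limma adjusted p = 0.142, 0.0561 and 0.143), and -0.44 to -0.22 leaving out 1 library. In CKO_K209A minus CKO_NAT10 it was 0.38 with the 2 groups alone and 0.24 without the interferon-high libraries (adjusted p = 0.07 and 0.0758), and 0.24 to 0.46 leaving out 1 library. In CKO_NAT10 minus ff_GFP Nat10 was -0.57 with the 2 groups alone, -0.43 without the interferon-high libraries and -0.46 without scaling (adjusted p = 0.093, 0.0549 and 0.0712), and -0.64 to -0.43 leaving out 1 library. In CKO_G641E minus ff_GFP it was -0.74 to -0.65 leaving out 1 library, and in CKO_K209A minus ff_GFP library weights gave -0.25 (adjusted p = 0.0399).

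The interferon list in CKO_GFP minus ff_GFP turned to -0.47 without the interferon-high libraries (limma adjusted p = 0.0294), a removal that takes 1 CKO_GFP library chosen for its level in this list and 0 of ff_GFP, and without CKO_GFP replicate 1 alone it was also -0.47 but not called (adjusted p = 0.454). The ribosomal protein list in CKO_K209A minus CKO_GFP turned to 0.12 with quantile normalization (adjusted p = 0.000536). The p53 and ATF4 lists kept their calls in CKO_G641E minus CKO_NAT10 in every alternative run for lists, which were the other list tests, a pseudocount of 1, the 4 other scalings, the block and leaving out libraries. The recovery score of CKO_K209A was -0.020 over every tested gene and -0.11 to 0.026 leaving out 1 library, and that of CKO_G641E was 0.712 to 0.787. At an adjusted p under 0.01 the overlaps of CKO_GFP minus ff_GFP were 2552 with CKO_NAT10 minus CKO_GFP, 2615 with CKO_G641E minus CKO_GFP, 213 with CKO_K209A minus CKO_GFP and 2893 with CKO_K209A minus CKO_NAT10, and CKO_NAT10 minus CKO_GFP shared 2232 with CKO_G641E minus CKO_GFP.

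The replicate numbers showed no pairing across all groups. Of 30 correlations of deviations between libraries with the same number, 4 were over 0.1, and no comparison had all 3 over 0.1. In all, 5 libraries correlated best with their own number. In CKO_G641E minus CKO_NAT10 the 3 correlations were 0.0883, 0.364 and 0.115, so a pairing of these 2 groups is not excluded. The value of 0.364 is that of replicate 2, which in both groups was among the 3 libraries highest in interferon-stimulated genes. A pairing cannot be told apart here from that shared feature. With the replicate number as a block, CKO_GFP minus ff_GFP gave 6127 genes, CKO_K209A minus CKO_GFP 1139 and CKO_G641E minus CKO_NAT10 8. No count moved by over 1.5 times, and with the block Atf3 was not called in CKO_G641E minus CKO_NAT10.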

Other observations

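The tests of explanations in this section were chosen after the results were seen, except the regrouping of libraries, which was planned beforehand. Acta1, which encodes skeletal alpha-actin, did not follow most of the 18 fetal and stress genes, of which 14 fell in CKO_NAT10 against CKO_GFP (2 rose and 2 were not called) and 12 in CKO_G641E (2 rose and 4 were not called). It measured 62.9 ± 29.8 FPKM in ff_GFP and 237 ± 63.3 in CKO_GFP, and stayed at 207 ± 89.5 in CKO_NAT10 and 227 ± 79.7 in CKO_G641E (SD, n = 3), above ff_GFP by log2 1.76 and 1.92 (limma adjusted p = 0.042 and 0.034). In CKO_K209A it measured 94.9 ± 0.858 FPKM (log2 -1.28 against CKO_GFP, adjusted p = 0.0775). The calls of Acta1 in CKO_NAT10 and CKO_G641E against ff_GFP ended when the 2 groups were fitted alone and when ff_GFP replicate 1 or 2 was left out.

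Lgals3, which encodes galectin-3, measured 1.02 ± 0.378 FPKM in ff_GFP, 13.7 ± 4.55 in CKO_GFP and 3.99 ± 0.348 in CKO_K209A (SD, n = 3; log2 -1.61 against CKO_GFP, limma adjusted p = 0.00688, and 0.0947 with the 2 groups fitted alone). In that comparison 4 of 18 macrophage markers fell (camera adjusted p = 0.00296, but adjusted p = 0.555 with an estimated correlation). The recovery score over the 9 called macrophage markers was 0.906 ± 0.122 in CKO_NAT10, 0.792 ± 0.249 in CKO_G641E and 0.582 ± 0.0279 in CKO_K209A, where the score over all called genes was -0.0696. Over 5 called ubiquitin ligase and muscle atrophy genes the CKO_K209A score was 0.527 ± 0.197. The CKO_GFP libraries themselves ran from -0.465 to 0.596 over these genes (-0.0539 ± 0.569), so the CKO_K209A mean lies within their range.

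Interferon-stimulated genes were high in CKO_GFP replicate 1, CKO_NAT10 replicate 2 and CKO_G641E replicate 2, with medians of 2.77, 2.15 and 1.48 log2 units above the other libraries of their groups. More macrophages alone may be a cause, but in each of the 3 libraries the upper quartile of the macrophage markers' rise, at most 0.832, lay below the lower quartile of the interferon-stimulated genes, at least 1.13. More lymphocytes, natural killer cells or neutrophils cannot be told apart from other causes, because only 6 of 16 markers passed the filter (upper quartile of their rise at most 1.40). Nkg7, a gene of T and natural killer cells below the filter, measured 2.07 FPKM in CKO_GFP replicate 1 against 0.163 and 0.0732 in replicates 2 and 3, and 0.695 in CKO_G641E replicate 2 against 0.0788 and 0.208, and was listed at 0 in CKO_NAT10 replicate 2. Sex alone could be another cause, but 3 libraries were out of place, since 4 libraries were Xist-high and only 2 of them were among the 3. CKO_G641E replicate 2 was not Xist-high, and ff_GFP replicate 1 and CKO_GFP replicate 2 were Xist-high but not among the 3. With 3 set against 4, at least 1 library had to be out of place. As 2 of the 3 were Xist-high, a part played by sex is not excluded.

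The p53 targets were lower and the ATF4 genes higher in CKO_G641E than in CKO_NAT10. For the p53 targets this may mean that the CKO_G641E hearts lay nearer to ff_GFP throughout. Over 6173 called genes outside both lists, however, the scores differed by 0.0117, against 0.207 for the p53 list. The ATF4 list, at -0.329, runs the other way by the pattern itself, so it is no separate test. The pattern of both lists could come from the Xist-high CKO_NAT10 replicate 2, but without that library the higher adjusted p of the 2 lists was 9.55e-07 (camera of limma). Different levels of the 2 transgenes cannot be told apart from an effect of the substitution, as Nat10 reads differed by -0.12 and transgene reads were not listed.

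No group given NAT10 was called higher in Nat10 reads than CKO_GFP. In hearts that had lost Nat10 the transgene may not have worked, but the lowest recovery score among the 6 libraries of CKO_NAT10 and CKO_G641E was 0.658, against at most 0.212 in CKO_GFP. Hearts that kept Nat10 undeleted cannot be told apart from hearts with a working transgene: the highest Nat10 level in these 6 libraries was 2.92 FPKM and the lowest in ff_GFP 3.87, but Nat10 reads did not separate CKO_GFP from ff_GFP either (limma adjusted p = 0.165). A transgene whose sequence is not counted under the mouse gene cannot be told apart from a low transgene level (log2 -0.36 in CKO_NAT10 against CKO_GFP).

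When the 6 libraries of a comparison were regrouped into all 10 splits of 3 and 3, only 1 split, the real one, reached its count in each of the 10 comparisons, so the share cannot go below 0.1. Every other split holds libraries of both groups on each side. A difference between the groups then adds to the spread within each side, so low counts in those splits are in part built in. The real count and the highest of the other splits were 6212 and 20 for CKO_GFP minus ff_GFP, 4776 and 1 for CKO_NAT10 minus CKO_GFP, 4793 and 1 for CKO_G641E minus CKO_GFP, and 1215 and 13 for CKO_K209A minus CKO_GFP. They were 8 and 1 for CKO_G641E minus CKO_NAT10, 6363 and 1 for CKO_K209A minus CKO_NAT10, and 6250 and 1 for CKO_K209A minus CKO_G641E. Against ff_GFP they were 378 and 0 for CKO_NAT10, 274 and 3 for CKO_G641E, and 7307 and 0 for CKO_K209A.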
